A study of Mus musculus with 24 samples.

How the data were processed

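The data were gene-level read counts from C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes when serum is withdrawn. Cells were grown in 10% fetal bovine serum and differentiated in 2% horse serum, per the labels' protocols. During differentiation they received a vehicle, 100 µM linoleic acid (LA, an omega-6 fatty acid) bound to albumin, or ANGPTL4 protein of mouse sequence at 10 ng/mL. ANGPTL4 is a secreted protein that inhibits lipoprotein lipase. Cells were collected at day 2 or day 6. The 6 groups held 4 libraries each.

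Libraries were made from total RNA of an integrity number above 7 with the QuantSeq 3′ kit, per the labels' protocols, so a library holds reads from transcript ends. Trimmomatic, STAR 2.7.1a, HTSeq 0.9.1, DESeq2 and DESeq were named with the mouse build mm39, per the submitters' processing notes, which gave neither their order nor their settings. The deposited values were raw counts, whole numbers per gene symbol, for 14693 genes. The lowest total of a gene over the 24 libraries was 51 counts. By its name the table was deposited as raw filtered counts, and how genes were removed was not stated. No annotation of mm39 was used here. Gene names were taken as in the table, and transcript length and GC content came from an annotation of another mouse build for 14501 genes (98.7%), with the last 500 nucleotides of a transcript as its end. No coordinates are given.

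Counting and strand settings were not described. Values of genes with near-identical copies, such as ribosomal protein genes, Ftl1, Fth1, Hspa1b, Ifit3, Ifit3b, Hmga1b, H2-Q4 and Ces1a, are therefore uncertain, as are values of genes that overlap another gene or run antisense to it, such as Mir1a-1hg and genes with Rik or Gm names.

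Genes with low counts were removed with edgeR's filterByExpr on the groups, which left 12994 genes and removed 1699. Counts were scaled with edgeR 4.0.16 (TMM factors) in R 4.3.3. All 24 libraries were fitted in one model of group means with edgeR's robust quasi-likelihood method, with 18 residual degrees of freedom. The common biological coefficient of variation was 6.51%. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. Every adjusted p of a gene in the text comes from this test unless another tool is named. Counts of list members are given adjusted over all genes and again over the list alone. Log2 fold changes are written log2FC, and where 2 p-values stand for a list, the second is that with an estimated correlation. Standard errors (SE) of genes are approximate, from the log2 fold change and its F statistic. Values in CPM, counts scaled to a common library total, use TMM-scaled totals, and log2 CPM for the principal components used a prior count of 2.

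Comparisons were LA against vehicle, ANGPTL4 against vehicle and LA against ANGPTL4 at each day, day 6 against day 2 in vehicle, and, for each treatment, the difference between its effects at day 6 and day 2. Lists of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with a correlation estimated for each list. Of 32 lists, 30 had the minimum of 5 tested members. The list of mitochondrially encoded genes had 0 members in the deposited table, and the list of macrophage markers had too few. The lists covered muscle differentiation, Wnt signalling, lipid metabolism, stress responses, extracellular matrix, growth, energy production and markers of other cell types.

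Named genes were chosen by a rule. It took 15 genes of lipid metabolism, myogenesis and Wnt signalling in every comparison of a treatment with vehicle. It added the 8 highest and 8 lowest fold changes among called genes with at least 5 CPM in the higher group and no overlap between the groups' libraries (5 and 5 in other comparisons). It also added up to 3 called members of each list that passed, and of the Wnt, PPAR, sarcomere and myogenic regulator lists in any case. The examples printed were picked among the genes so named after their values were seen, with preference for calls that held under the alternatives, so they are steadier than the named genes as a whole. A result on a withheld item is not reported. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

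Alternatives were DESeq2 size factors, no low-count filter, a filter of 5 CPM in at least 4 libraries, limma-voom, DESeq2 1.42.0, only the compared groups in the fit, the replicate number as a block, an estimated list correlation and each library left out in turn. After seeing the data, 5 more were chosen: a covariate for the factor along which libraries varied within their groups, removal of each library's trend with transcript length and GC content (mgcv 1.9.3), thinning of all libraries to the smallest total, leaving out the libraries that stood apart on the second principal component, and library totals without a scaling factor.

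Library totals ranged from 6.101 to 25.05 M counts. A count of 3, taken as the floor, was 0.120 CPM in the deepest library and 0.492 CPM in the shallowest, which covers counting error only. The procedure was tested on simulated counts with known fold changes. In simulated LA against vehicle at day 2 (12819 genes) it recovered 62.7%, 82.1% and 89.4% of genes changed 1.25-, 1.5- and 2-fold, with 8 false calls among 164. For ANGPTL4 against vehicle at day 2 (12833 genes) it recovered 46.3%, 80.6% and 90.6% at those sizes, with 6 false among 149. For LA at day 6 (12834 genes) these were 44.8%, 74.2% and 81.8%, with 11 false among 144, and for ANGPTL4 at day 6 (12836 genes) 45.5%, 76.1% and 93.9%, with 3 false among 146. For time in vehicle (12842 genes) they were 43.3%, 68.7% and 87.9%, with 10 false among 143. For the change of the LA effect between days (12831 genes) they were 13.4%, 74.2% and 72.7%, with 6 false among 112.

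The labels do not say whether the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries.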

Results

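Transcript abundance was measured by 3′ end sequencing in differentiating C2C12 myoblasts given vehicle, LA or ANGPTL4, at day 2 and day 6, with 4 libraries in each of the 6 groups. At day 2, library totals were 9.85 to 14.5 M counts with vehicle (mean 11.97 ± 1.98, SD, n = 4), 9.55 to 25.05 M with LA (19.2 ± 7.31) and 13.2 to 20.6 M with ANGPTL4 (16.6 ± 3.45). At day 6 they were 9.85 to 12.6 M with vehicle (11.3 ± 1.44), 8.19 to 15.2 M with LA (10.98 ± 3.00) and 6.101 to 9.07 M with ANGPTL4 (7.66 ± 1.22). The ANGPTL4 totals at day 6 lay below the vehicle totals by more than the spread of these libraries (difference -3.64 M, 2-sided exact permutation p = 0.0286, the smallest that 70 splits allow, 0.0914 after adjustment over 16 such tests). The study set out, per its labels, to find genes that respond to LA and to ANGPTL4 while myoblasts differentiate, and its title names the Wnt pathway.

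Day separated the libraries on the first principal component, which held 47.5% of the variance, and the second held 9.46%. At day 2 the second component averaged 12.9 with vehicle, -2.80 with LA and -14.4 with ANGPTL4 (exact permutation p = 0.0286 for LA and 0.0286 for ANGPTL4 against vehicle, 0.0914 after adjustment for each). The day 2 LA replicate 3 lay apart from its group on this component at -19.3, and the day 6 ANGPTL4 replicate 1 lay apart at 18.7. Within groups, the 36 pairs of libraries correlated across genes with Pearson r of 0.986 to 0.997.

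**Figure D1:**
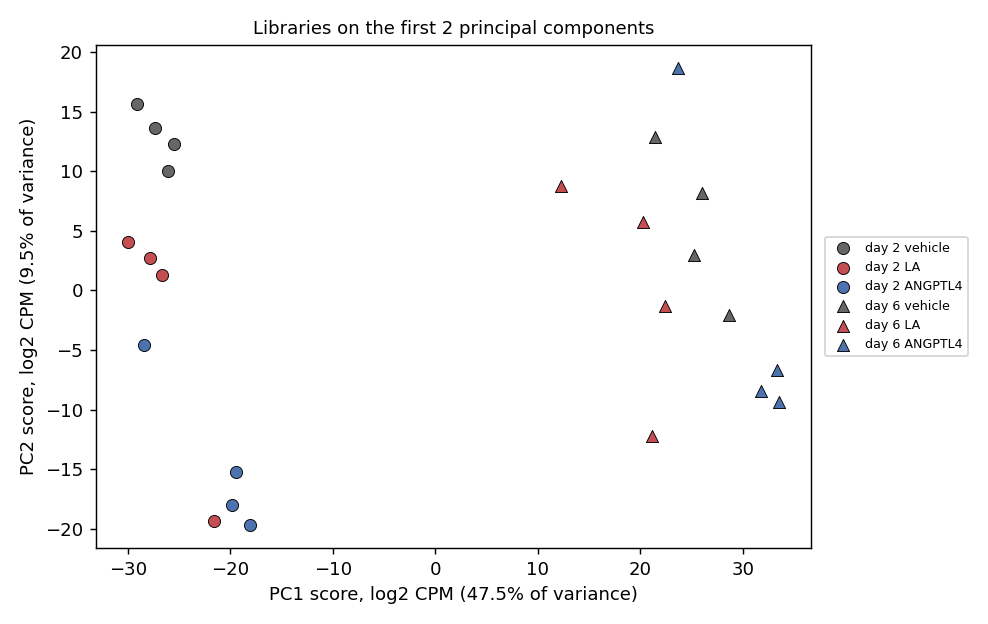
Scores of the 24 libraries on the first and second principal components of log2 CPM, each point 1 library, coloured by treatment and shaped by day. The first component (47.5% of the variance) parts day 2 from day 6, and the second (9.46%) runs from day 2 vehicle to day 2 ANGPTL4 and also spreads the libraries of day 6.

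Vehicle libraries of day 6 and day 2 gave the course of differentiation without treatment. Transcripts of the contractile apparatus rose. In the sarcomere list 50 of 58 members rose and 3 fell, 50 and 3 over the list alone (median log2FC 0.65, adjusted p = 1.83e-47, 0.00407 with an estimated correlation). Mybpc2, which encodes a fast-type myosin-binding protein, rose from 1.31 ± 0.306 to 23.5 ± 2.23 CPM (mean ± SD, n = 4; log2FC 4.13, SE 0.159, adjusted p = 1.46e-19). In the muscle energy list 18 of 22 members rose and 1 fell, 18 and 1 over the list alone (median log2FC 0.66, adjusted p = 2.93e-11, adjusted p = 0.0230 with an estimated correlation).

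Regulators of myogenesis moved both ways. Mef2c, a late myogenic transcription factor, rose from 242 ± 16.5 to 783 ± 17.1 CPM (log2FC 1.69, SE 0.0748, adjusted p = 1.14e-16). Over the myogenic regulator list 7 of 20 members rose and 10 fell, 7 and 10 over the list alone, and its median (-0.14) and mean (0.093) differed in sign (adjusted p = 0.750). Pax7, a satellite cell transcription factor, fell (log2FC -1.10, SE 0.0858, adjusted p = 3.54e-12). In the satellite and reserve cell list 5 of 19 members rose and 10 fell, 6 and 10 over the list alone (median log2FC -0.23, adjusted p = 0.00310, adjusted p = 0.0533 with an estimated correlation). In the cell cycle list 30 of 48 members fell, 30 over the list alone (median log2FC -0.34, adjusted p = 2.33e-07, adjusted p = 0.324 with an estimated correlation). Transcripts of excitation-contraction coupling rose (21 of 31 members rose and 4 fell, 21 and 5 over the list alone, median log2FC 0.33, adjusted p = 1.01e-05, adjusted p = 0.180 with an estimated correlation).

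Lpl, which encodes lipoprotein lipase, fell most among the genes named in vehicle, from 51.7 ± 10.2 to 6.06 ± 1.97 CPM (log2FC -3.09, SE 0.232, adjusted p = 2.11e-09). Each gene named here kept its direction in 16 of 16 pairs of a day 6 and a day 2 library. In the edgeR test 5930 genes changed, 3272 higher and 2658 lower at day 6 (55.2% higher), of which 436 rose and 332 fell at least 2-fold. The share higher was 49.7% with DESeq2 size factors and 46.4% with library totals alone.

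LA against vehicle at day 2 asked what the fatty acid changed early in differentiation. Transcripts that respond to fatty acids rose. Angptl4, the transcript of the protein given in the other treatment, rose from 20.2 ± 1.79 to 81.7 ± 1.32 CPM (mean ± SD, n = 4; log2FC 2.01, SE 0.0650, adjusted p = 2.15e-21). Cpt1a, which encodes the enzyme that lets long-chain fatty acids into mitochondria, rose from 88.0 ± 5.34 to 141 ± 0.760 CPM (log2FC 0.68, SE 0.0480, adjusted p = 1.35e-11). Plin2, a lipid droplet coat protein, rose from 75.8 ± 3.97 to 103 ± 3.47 CPM (log2FC 0.45, SE 0.0506, adjusted p = 1.57e-06). All 3 were higher in 16 of 16 pairs of an LA and a vehicle library. Pdk4, which restrains glucose oxidation, had no call at day 2 (log2FC 0.017, SE 0.112, adjusted p = 0.941). In the list of targets of PPAR, nuclear receptors for fatty acids, 19 of 40 members rose, 23 over the list alone (median log2FC 0.22, adjusted p = 2.28e-18, 0.00200 with an estimated correlation). In the oxidative stress list 11 of 32 members rose, 19 over the list alone (median log2FC 0.17, adjusted p = 2.56e-07, adjusted p = 0.223 with an estimated correlation), with Slc7a11, a cystine transporter, at 1.43 (SE 0.256, adjusted p = 0.00225, higher in 15 of 16 pairs, but 0.0567 with only the compared groups fitted, range 3.03e-06 to 0.0567). In the hypoxia list, which includes Angptl4, 8 of 34 members rose, 9 up and 1 down over the list alone (median log2FC 0.073, adjusted p = 2.86e-05, adjusted p = 0.223 with an estimated correlation).

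**Figure D2:**
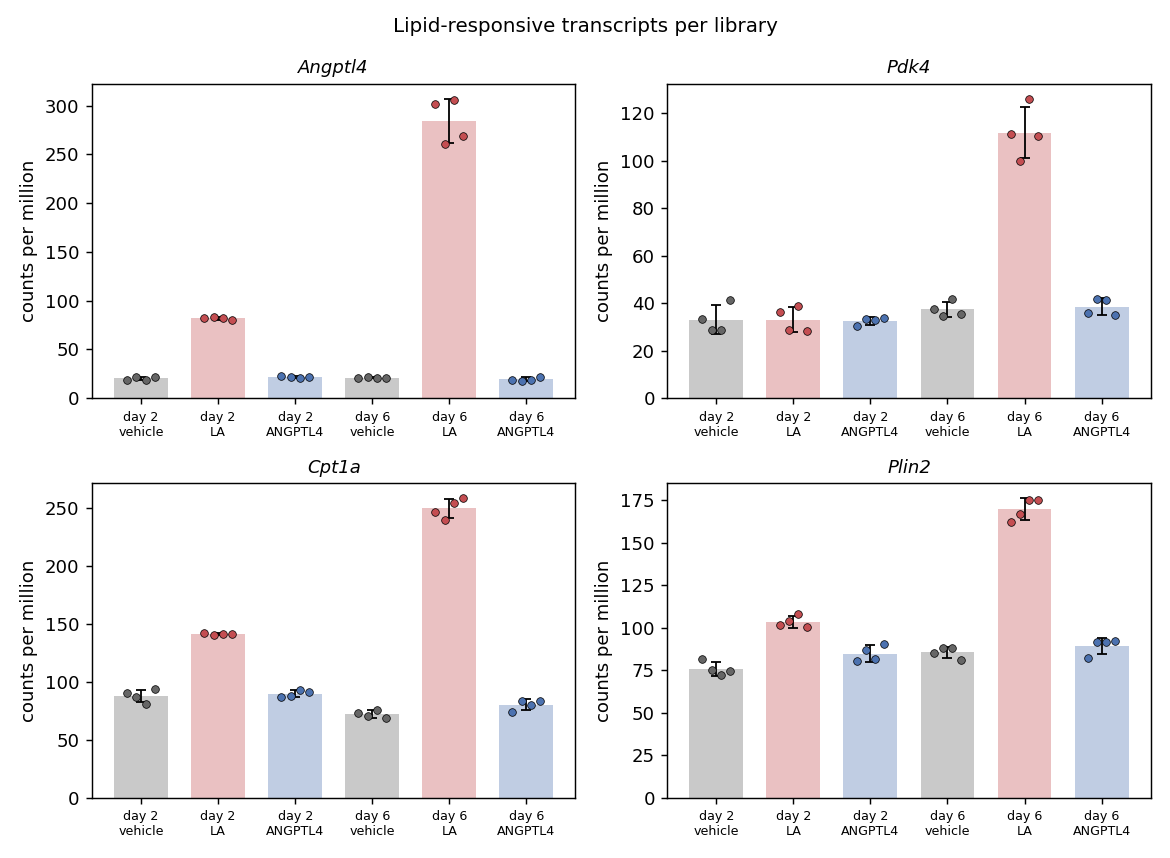
CPM of Angptl4, Pdk4, Cpt1a and Plin2 in the 6 groups, with each point 1 library, bars at group means and error bars of 1 SD (n = 4). Angptl4 averaged 81.7 CPM with LA at day 2 and 285 CPM at day 6, against 19.1 to 21.6 CPM in the vehicle and ANGPTL4 groups.

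At day 2, 1 of 20 myogenic regulators rose and 4 fell. Myod1 (0.075, SE 0.0528, adjusted p = 0.362) and Myog (0.13, SE 0.0641, adjusted p = 0.178), which start myogenesis, did not pass. Of fusion genes, Mymx rose (0.38, adjusted p = 0.00144) but Mymk (0.077, adjusted p = 0.480) did not pass. Nor did actin Acta1 (0.011, adjusted p = 0.915) or creatine kinase Ckm (0.20, adjusted p = 0.201). Fast myosin Myh4 fell from 244 ± 19.1 to 172 ± 17.1 CPM (log2FC -0.50, SE 0.103, adjusted p = 0.00404). Embryonic myosin Myh3 fell by less (log2FC -0.19, SE 0.0608, adjusted p = 0.0289). The call ended without day 2 vehicle replicate 2 (0.0867), 3 (0.0563) or 4 (0.0552), or LA replicate 1 (0.0940) or 3 (0.109), or in 4 other settings (up to 0.164, with length and GC removed) (range of adjusted p over the alternatives 0.0120 to 0.164). The sarcomere list (median log2FC -0.036, adjusted p = 0.294) and the myogenic regulator list (median -0.00081, mean 0.0021, adjusted p = 0.722) did not pass.

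Wnt transcripts moved both ways at day 2. Lef1, a transcription factor of the Wnt pathway, fell from 18.6 ± 2.04 to 14.6 ± 1.45 CPM (log2FC -0.35, SE 0.0930, adjusted p = 0.0124, lower in 15 of 16 pairs). It lost the call without day 2 vehicle replicate 4 (0.0723), or with only the compared groups (0.0567) or the libraries apart left out (0.0532) (range 0.00705 to 0.0723). Apc, part of the complex that degrades beta-catenin, fell (log2FC -0.28, SE 0.0600, adjusted p = 0.00303), while Ccn5, a secreted growth regulator, rose (log2FC 0.40, SE 0.0750, adjusted p = 0.00136). Ctnnb1, which encodes beta-catenin (log2FC 0.11, SE 0.0433, adjusted p = 0.0872), Axin2 (-0.092, adjusted p = 0.555), Ccnd1 (0.16, adjusted p = 0.265) and Myc (-0.034, adjusted p = 0.820) did not pass. None of the Wnt lists passed. This held for the core pathway (median log2FC -0.013, adjusted p = 0.573), beta-catenin targets (median log2FC -0.041, adjusted p = 0.722) and antagonists (median log2FC 0.061, adjusted p = 0.722).

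The ribosomal protein and oxidative phosphorylation lists were higher in 3 of 4 LA libraries at day 2. In the ribosomal protein list 58 of 76 members rose, 72 over the list alone (median log2FC 0.58, adjusted p = 2.37e-37). In the oxidative phosphorylation list 42 of 64 members rose, 52 over the list alone (median log2FC 0.43, adjusted p = 3.78e-22), but with an estimated correlation neither passed (adjusted p = 0.223 for each). The list scores of day 2 LA replicate 4 (-0.118 and -0.159, mean log2 CPM around the mean of all libraries) lay within those of vehicle (-0.461 to -0.0145 and -0.261 to -0.0769). The other LA libraries had 0.488 to 0.676 and 0.229 to 0.424. Ribosomal protein genes held 2.55 ± 0.450% of counts with LA and 1.82 ± 0.198% with vehicle (exact permutation p = 0.0571, 0.152 after adjustment). In the atrophy and autophagy list 7 of 23 members rose and 2 fell, 10 and 2 over the list alone (median log2FC 0.11, adjusted p = 0.0337, adjusted p = 0.385 with an estimated correlation). The list lost its call without day 2 vehicle replicate 2 (0.0870) or 3 (0.0570), or LA replicate 2 (0.0764) or 3 (0.0529), or in 4 other settings (up to 0.0790, with only the compared groups) (range 0.00770 to 0.385).

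In all, 1961 genes changed with LA at day 2, 1075 higher and 886 lower (54.8% higher), of which 29 rose and 15 fell at least 2-fold. DESeq2 called 2051 and limma-voom 2130. The share higher was 47.6% with DESeq2 size factors and 68.2% with library totals alone. The count dropped to 632 without day 2 LA replicate 3 and to 1109 without day 2 vehicle replicate 4, and to 422 when only the compared groups were fitted. Of 45 called named genes, 28 kept the call when any 1 library was left out.

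LA against vehicle at day 6 asked the same of cells late in differentiation. Lipid transcripts rose at this day too. Angptl4 rose from 20.8 ± 0.759 to 285 ± 22.8 CPM (mean ± SD, n = 4; log2FC 3.77, SE 0.0656, adjusted p = 6.17e-30), and Cpt1a rose from 72.2 ± 3.24 to 249.8 ± 8.20 CPM (log2FC 1.79, SE 0.0494, adjusted p = 7.18e-24). Pdk4, with no call at day 2, rose from 37.4 ± 3.07 to 112 ± 10.9 CPM (log2FC 1.58, SE 0.108, adjusted p = 3.50e-10). Plin2 rose from 85.6 ± 3.20 to 169.7 ± 6.297 CPM (log2FC 0.99, SE 0.0507, adjusted p = 9.91e-16). Lpl rose from 6.06 ± 1.97 to 37.8 ± 9.50 CPM (log2FC 2.63, SE 0.240, adjusted p = 2.22e-07). Each was higher in 16 of 16 pairs. In the PPAR target list 19 of 40 members rose, 19 up and 1 down over the list alone (median log2FC 0.24, adjusted p = 2.31e-38, 1.25e-05 with an estimated correlation). Sterol synthesis transcripts were lower (9 of 25 members fell, 12 over the list alone, median log2FC -0.15, adjusted p = 1.44e-06, adjusted p = 0.171 with an estimated correlation).

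Muscle transcripts fell with LA at day 6. In the sarcomere list 47 of 58 members fell, 50 over the list alone (median log2FC -0.40, adjusted p = 2.42e-33, 0.00460 with an estimated correlation). In the excitation-contraction coupling list 24 of 31 members fell, 27 over the list alone (median log2FC -0.37, adjusted p = 4.97e-26, 0.00113). The giant filament protein Neb fell from 3118 ± 235 to 2024 ± 131 CPM (log2FC -0.62, SE 0.0972, adjusted p = 5.81e-05). Acta1 fell from 3924 ± 172 to 2907 ± 183 CPM (log2FC -0.43, SE 0.0514, adjusted p = 1.90e-07). Myh3 fell (log2FC -0.45, SE 0.0610, adjusted p = 1.35e-06). In the muscle energy list 1 of 22 members rose and 12 fell, 1 and 13 over the list alone (median log2FC -0.33, adjusted p = 1.01e-07, 0.0318 with an estimated correlation).

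Regulators of differentiation and fusion fell alongside. Myod1 fell from 140.1 ± 3.43 to 113 ± 7.02 CPM (log2FC -0.31, SE 0.0547, adjusted p = 7.55e-05). Mymk, needed for myoblast fusion, fell from 489 ± 62.7 to 324 ± 27.4 CPM (log2FC -0.59, SE 0.0689, adjusted p = 2.06e-07). Myog fell from 806 ± 32.8 to 682 ± 49.1 CPM (log2FC -0.24, SE 0.0644, adjusted p = 0.00723). This call was lost without day 6 LA replicate 2 (0.0656) or 4 (0.0539) (range 0.00129 to 0.0656). Ckm was lower at -0.32 (SE 0.106, adjusted p = 0.0425). The call did not hold without day 6 vehicle replicate 1 (0.161), 2 (0.0884), 3 (0.0531) or 4 (0.0530), or LA replicate 2 (0.131), 3 (0.0526) or 4 (0.140), or in 5 other settings (up to 0.0855, with length and GC removed) (range 0.00104 to 0.161). Cdkn1a, which holds cells out of the cycle, fell (log2FC -0.59, SE 0.0670, adjusted p = 1.33e-07). In the myogenic regulator list 1 of 20 members rose and 12 fell, 1 and 14 over the list alone (median log2FC -0.23, adjusted p = 5.17e-06, 0.0114 with an estimated correlation). In the fusion list 3 of 20 members rose and 11 fell, 3 and 11 over the list alone (median log2FC -0.18, adjusted p = 0.000475, 0.0421).

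**Figure D3:**
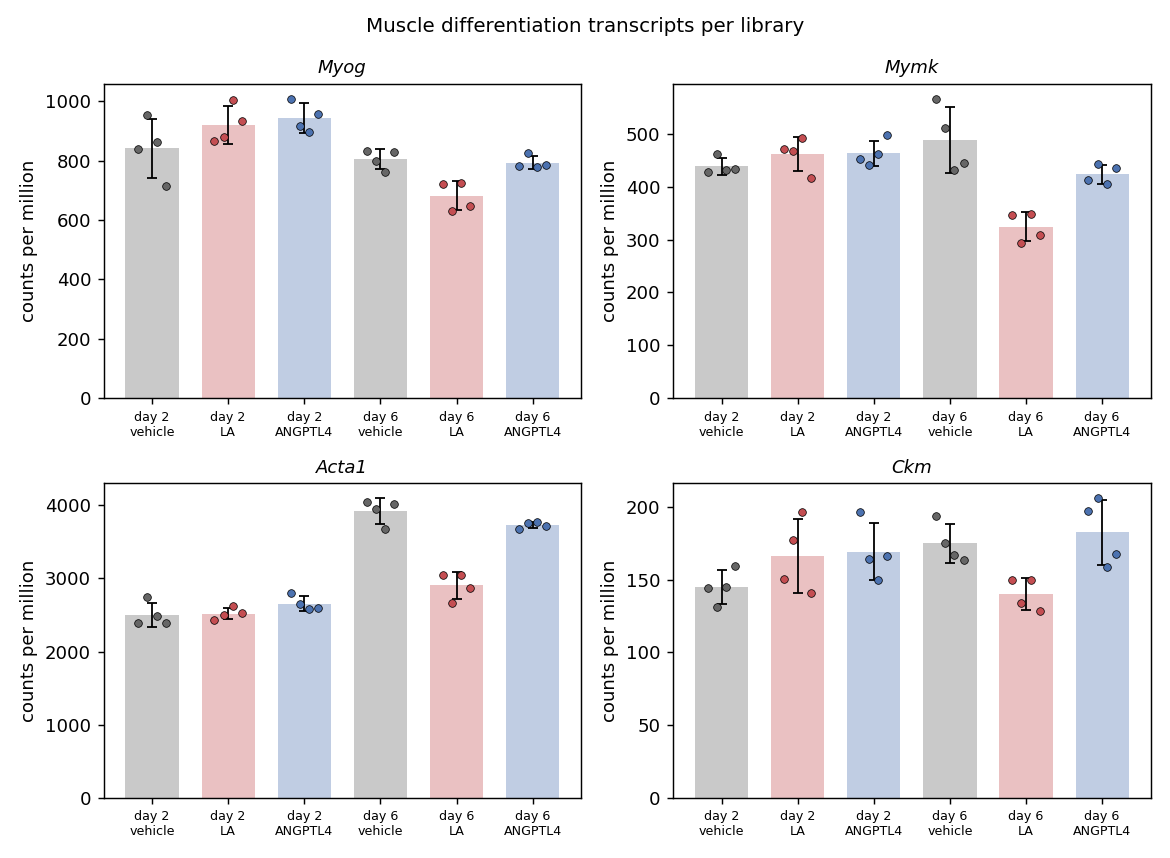
CPM of Myog, Mymk, Acta1 and Ckm in the 6 groups, with each point 1 library, bars at group means and error bars of 1 SD (n = 4). At day 6 all 4 averaged lower with LA than with vehicle, with Acta1 at 2907 against 3924 CPM, and with ANGPTL4 none of the 4 was called changed.

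The fibroblast and adipocyte marker lists were higher in the same libraries in which muscle transcripts fell. In the fibroblast marker list 9 of 14 members rose, 10 over the list alone (median log2FC 0.41, adjusted p = 1.01e-07, 0.00259 with an estimated correlation), with the growth factor receptor Pdgfra up (log2FC 0.69, SE 0.0820, adjusted p = 1.94e-07). In the adipocyte list 4 of 8 members rose, 4 over the list alone (median log2FC 0.31, adjusted p = 5.78e-05, 0.00259), and Lpl is a member of this list and of the PPAR list. The bone and cartilage list had a median of -0.053 and a mean of 0.48 (adjusted p = 0.0810), though its member Omd, a matrix protein of bone, rose (log2FC 1.88, SE 0.310, adjusted p = 0.000224). Smooth muscle (median -0.048, mean 0.0094, adjusted p = 0.371) and endothelial markers (median log2FC -0.014, adjusted p = 0.783) did not pass.

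Of the Wnt lists, that of secreted antagonists passed with LA at day 6, led by Sfrp1 (from 3.43 ± 0.921 to 12.02 ± 2.63 CPM; log2FC 1.78, SE 0.250, adjusted p = 1.62e-05) and Sfrp4 (log2FC 0.94, SE 0.134, adjusted p = 3.55e-06), which bind Wnt proteins. In the antagonist list 5 of 13 members rose and 1 fell, 6 and 1 over the list alone (median log2FC 0.38, adjusted p = 0.000523, 0.0356 with an estimated correlation). The ligands Wnt10a (log2FC -0.79, SE 0.112, adjusted p = 3.12e-06) and Wnt11 (log2FC -1.35, SE 0.245, adjusted p = 0.000122) fell. So did Porcn, an enzyme of Wnt secretion (log2FC -0.55, SE 0.0572, adjusted p = 1.99e-08). The core pathway list (median log2FC -0.020, adjusted p = 0.783) and the beta-catenin target list (median log2FC -0.065, adjusted p = 0.371) did not pass. Axin2, a feedback inhibitor of the pathway, was lower (log2FC -0.35, SE 0.102, adjusted p = 0.0138). Its call was lost without day 6 vehicle replicate 4 (0.0951), or LA replicate 2 (0.0558), or with length and GC removed (0.0715) or thinning (0.104) (range 0.0132 to 0.104). Ctnnb1 was higher by a small amount (log2FC 0.12, SE 0.0435, adjusted p = 0.0440). The call ended without day 6 vehicle replicate 1 (0.0804), 2 (0.0700), 3 (0.0631) or 4 (0.0701), or LA replicate 2 (0.0854) or 4 (0.147), or with the replicate block (0.0565) (range 0.00771 to 0.147). Lef1 (-0.17, adjusted p = 0.363), Ccnd1 (0.089, adjusted p = 0.582) and Myc (0.056, adjusted p = 0.721) did not pass.

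The oxidative stress and hypoxia lists rose with LA at day 6. In the oxidative stress list 17 of 32 members rose, 17 over the list alone (median log2FC 0.19, adjusted p = 1.37e-07, 0.0357 with an estimated correlation). In the hypoxia list 15 of 34 members rose and 3 fell, 16 and 3 over the list alone (median log2FC 0.17, adjusted p = 2.29e-12, 0.00791).

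In all, 2237 genes changed, 1018 higher and 1219 lower (45.5% higher), of which 102 rose and 33 fell at least 2-fold. DESeq2 called 2097 and limma-voom 2159, and the share higher was 59.1% with library totals alone. Of 81 called named genes, 63 kept the call when any 1 library was left out.

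The effects of LA at day 6 and day 2 were compared directly. The LA effect on lipid transcripts was greater at day 6 for Angptl4 (difference 1.77, SE 0.0929, adjusted p = 5.67e-15 in log2), Pdk4 (difference 1.56, SE 0.155, adjusted p = 7.53e-07), Cpt1a (difference 1.11, SE 0.0684, adjusted p = 3.19e-13) and Lpl (difference 2.29, SE 0.298, adjusted p = 5.19e-05). It was more negative at day 6 for Myod1 (difference -0.39, SE 0.0761, adjusted p = 0.000610), Mymk (difference -0.67, SE 0.0967, adjusted p = 2.48e-05) and Acta1 (difference -0.44, SE 0.0726, adjusted p = 8.02e-05). Over lists, the difference was negative for sarcomere transcripts (1 of 58 members had a greater effect and 36 a lower one, 1 and 44 over the list alone, median difference -0.32, adjusted p = 5.99e-16, adjusted p = 0.0806 with an estimated correlation) and for excitation-contraction coupling (median -0.42, adjusted p = 7.02e-15, 0.0386 with an estimated correlation). For Wnt antagonists it was positive (median 0.44, adjusted p = 0.0204, adjusted p = 0.155 with an estimated correlation), led by Sfrp1 (difference 1.89, SE 0.344, adjusted p = 0.000610). The list lost its call without day 2 LA replicate 4 (0.0579) (range 0.00493 to 0.155). In all, 2554 genes differed, 1128 with a higher and 1426 with a lower effect at day 6 (44.2% higher). The list calls apart from excitation-contraction coupling were lost with an estimated correlation.

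ANGPTL4 against vehicle at day 2 asked whether the protein itself changed the same transcripts early. Of 4 lipid genes, Plin2 alone was called. Angptl4 (from 20.2 ± 1.79 to 21.6 ± 0.590 CPM; log2FC 0.087, SE 0.0709, adjusted p = 0.463), Cpt1a (0.030, adjusted p = 0.735) and Pdk4 (-0.020, adjusted p = 0.936) did not pass. Plin2 was higher (log2FC 0.16, SE 0.0510, adjusted p = 0.0429, in 15 of 16 pairs). It lost the call without day 2 vehicle replicate 2 (0.102), 3 (0.156) or 4 (0.0946), or ANGPTL4 replicate 2 (0.135), 3 (0.0664) or 4 (0.189), or in 9 other settings (up to 0.428, with the within-group covariate) (range 0.0283 to 0.428). Myod1 rose from 159 ± 13.3 to 186 ± 5.00 CPM (log2FC 0.22, SE 0.0528, adjusted p = 0.00945, in 16 of 16 pairs). This call was lost without day 2 vehicle replicate 2 (0.0537), or with only the compared groups (0.0590) or the within-group covariate (0.210) (range 0.00515 to 0.210). Myog (0.17, adjusted p = 0.0945), Mymk (0.078, adjusted p = 0.496), Myh3 (-0.13, adjusted p = 0.161), Acta1 (0.087, adjusted p = 0.286) and Ckm (0.23, adjusted p = 0.174) did not pass.

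Ttn and Neb, which encode giant sarcomere proteins, fell with ANGPTL4 at day 2. Ttn fell from 15912 ± 1662 to 7827 ± 672 CPM (log2FC -1.02, SE 0.223, adjusted p = 0.0103), and Neb fell from 2805 ± 278 to 2066 ± 241 CPM (log2FC -0.44, SE 0.0969, adjusted p = 0.00859), each in 16 of 16 pairs. With the within-group factor as a covariate neither was called (0.184, range 7.62e-06 to 0.184, and 0.231, range 0.000217 to 0.231). The sarcomere list did not pass (4 of 58 members fell, 2 over the list alone), with a median of 0.0096, a mean of -0.031 and an adjusted p of 0.499. The myogenic regulator list did not pass (median log2FC 0.065, adjusted p = 0.499). The lowest fold change was of Mir1a-1hg, the host transcript of muscle microRNAs (from 11.4 ± 0.941 to 2.52 ± 1.30 CPM; log2FC -2.23, SE 0.470, adjusted p = 0.00870), not called with that covariate (0.170, range 2.34e-05 to 0.170). Noncoding genes held 1.95 ± 0.395% of counts with ANGPTL4 and 3.05 ± 0.374% with vehicle (exact permutation p = 0.0286, 0.0914 after adjustment).

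Wnt transcripts moved little at day 2. Lrp6, a coreceptor for Wnt, fell (log2FC -0.25, SE 0.0606, adjusted p = 0.0111), but had no call with the within-group covariate (0.385) or length and GC removed (0.0691) (range 0.00119 to 0.385). Lef1 fell (log2FC -0.33, SE 0.0937, adjusted p = 0.0239). The call did not hold without day 2 vehicle replicate 4 (0.102), or ANGPTL4 replicate 2 (0.0547) or 3 (0.0550), or in 4 other settings (up to 0.431, with the within-group covariate) (range 0.00732 to 0.431). Ctnnb1 (log2FC 0.13, SE 0.0433, adjusted p = 0.0528), Axin2 (-0.19, adjusted p = 0.206), Ccnd1 (0.037, adjusted p = 0.839) and Myc (0.074, adjusted p = 0.589) did not pass. Among lists, the core pathway (median log2FC 0.0074, adjusted p = 0.739), beta-catenin targets (median log2FC -0.00065, adjusted p = 0.785) and antagonists (median log2FC 0.14, adjusted p = 0.480) did not pass.

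No list call with ANGPTL4 at day 2 was left with an estimated correlation, whose adjusted p stands second for each list. The PPAR targets were higher (7 of 40 members rose, 8 over the list alone, median log2FC 0.15, adjusted p = 0.000210 and 0.350). So was the oxidative stress list (5 of 32 members rose, 8 over the list alone, median log2FC 0.13, adjusted p = 0.00166 and 0.617). Oxidative phosphorylation was higher (12 of 64 members rose, 16 over the list alone, median log2FC 0.20, adjusted p = 4.59e-12 and 0.617). So were ribosomal proteins (16 of 76 members rose, 25 over the list alone, median log2FC 0.31, adjusted p = 7.13e-17 and 0.617). Ribosomal protein genes held 2.27% of counts with ANGPTL4 and 1.82% with vehicle (exact permutation p = 0.0286, 0.0914 after adjustment). The immediate early and heat shock list was higher (6 of 28 members rose, 6 over the list alone, median log2FC 0.15, adjusted p = 0.00390 and 0.307). The unfolded protein list was higher (2 of 39 members rose, 2 over the list alone, median log2FC 0.086, adjusted p = 0.0240 and 0.650). Its call was lost without day 2 vehicle replicate 1 (0.0564) or 4 (0.0559), or ANGPTL4 replicate 1 (0.294), or in 3 other settings (up to 0.428, with the within-group covariate) (range 0.0104 to 0.650). The bone and cartilage list was lower (3 of 7 members fell, 3 over the list alone, median log2FC -0.093, adjusted p = 0.0240 and 0.617), with the hypertrophic collagen Col10a1 at -1.71 (SE 0.289, adjusted p = 0.00184, 0.178 with the covariate, range 3.88e-05 to 0.178). The list lost its call without day 2 vehicle replicate 4 (0.129), or ANGPTL4 replicate 1 (0.0570), 2 (0.0711) or 3 (0.0645), or in 4 other settings (up to 0.306, with the stricter filter) (range 0.00356 to 0.617).

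In all, 1276 genes changed with ANGPTL4 at day 2, 502 higher and 774 lower (39.3% higher), and 155 fell at least 2-fold. DESeq2 called 1242 and limma-voom 1377. The share higher was 27.1% with DESeq2 size factors and 54.2% with library totals alone. The count dropped to 712 without day 2 vehicle replicate 4 and to 821 without day 2 ANGPTL4 replicate 4, and to 1 with the factor along which libraries varied within groups as a covariate. Of 48 called named genes, 10 kept the call when any 1 library was left out.

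ANGPTL4 against vehicle at day 6 asked what the protein changed late. Naalad2, a peptidase, rose from 12.4 ± 0.755 to 17.7 ± 1.05 CPM (log2FC 0.51, SE 0.0889, adjusted p = 0.0314), and Dld, a subunit of mitochondrial dehydrogenases, rose from 243 ± 2.99 to 289 ± 9.46 CPM (log2FC 0.25, SE 0.0468, adjusted p = 0.0359). The kinase Sik1 fell from 178 ± 8.52 to 147 ± 9.99 CPM (log2FC -0.28, SE 0.0542, adjusted p = 0.0467). Each moved in 16 of 16 pairs, and these were the 3 genes that edgeR called, while 1513 had an unadjusted p under 0.05, DESeq2 called 87 and limma-voom 3. Naalad2's call was lost without day 6 vehicle replicate 1 (0.162) or 2 (0.105), or ANGPTL4 replicate 2 (0.209) or 3 (0.133), or with the replicate block (0.0706) or thinning (0.145) (range 0.0144 to 0.209). Dld's was lost without day 6 vehicle replicate 1 (0.162), 2 (0.163), 3 (0.103) or 4 (0.0567), or ANGPTL4 replicate 2 (0.287), 3 (0.133) or 4 (0.152), or in 5 other settings (up to 0.111, with length and GC removed) (range 0.000589 to 0.287). Sik1's was lost without day 6 vehicle replicate 1 (0.239), 2 (0.105), 3 (0.162) or 4 (0.0567), or ANGPTL4 replicate 2 (0.287), 3 (0.133) or 4 (0.152), or in 4 other settings (up to 0.0871, with the replicate block) (range 0.00249 to 0.287). EdgeR's count was 0 without day 6 vehicle replicate 1, vehicle replicate 2, ANGPTL4 replicate 2 or ANGPTL4 replicate 3, 1 without vehicle replicate 3 or ANGPTL4 replicate 4, 2 without vehicle replicate 4, and 7 without ANGPTL4 replicate 1.

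Named lipid and muscle genes did not pass at day 6. This held for Angptl4 (log2FC -0.12, SE 0.0813, adjusted p = 0.598), Cpt1a (log2FC 0.15, SE 0.0520, adjusted p = 0.208), Pdk4 (0.041, adjusted p = 0.931) and Plin2 (0.064, adjusted p = 0.675). It also held for Myod1 (-0.091, adjusted p = 0.540), Myog (-0.022, adjusted p = 0.932), Mymk (-0.21, adjusted p = 0.208), Myh3 (-0.069, adjusted p = 0.699), Acta1 (-0.072, adjusted p = 0.612) and Ckm (0.059, adjusted p = 0.873). The PPAR list (median log2FC 0.026, adjusted p = 0.346) and the myogenic regulator list (median log2FC -0.032, adjusted p = 0.469) did not pass.

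The beta-catenin target list was lower with ANGPTL4 at day 6, with 2 of 25 members above 0 (median log2FC -0.12, adjusted p = 0.000123, 0.00709 with an estimated correlation). It passed in each alternative and without any 1 library, with adjusted p up to 0.00709. Its member with the smallest p, Porcn, did not pass alone (log2FC -0.17, SE 0.0576, adjusted p = 0.207). Neither did Axin2 (-0.16, adjusted p = 0.578), Lef1 (-0.14, adjusted p = 0.697), Ccnd1 (-0.057, adjusted p = 0.861), Myc (-0.12, adjusted p = 0.634) or Ctnnb1 (0.026, adjusted p = 0.863). The core pathway list was lower (14 of 47 above 0, median log2FC -0.042, adjusted p = 0.0303, adjusted p = 0.234 with an estimated correlation). The call ended without day 6 vehicle replicate 2 (0.0620) or 3 (0.0605), or ANGPTL4 replicate 4 (0.104), or in 3 other settings (up to 0.114, with thinning) (range 0.0256 to 0.234). The antagonist list did not pass (median log2FC -0.079, adjusted p = 0.205).

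Other list calls at day 6 had medians within 0.1 of 0 and were lost with an estimated correlation, whose adjusted p stands second. The sarcomere list was higher (39 of 58 above 0, median log2FC 0.050, adjusted p = 0.0185 and 0.834). It lost the call without day 6 vehicle replicate 3 (0.0897), or ANGPTL4 replicate 2 (0.0916), or with the within-group covariate (0.0600) (range 3.48e-06 to 0.834). The excitation-contraction coupling list was lower (median log2FC -0.075, adjusted p = 0.0207 and 0.740). This call was lost without day 6 vehicle replicate 1 (0.0677) or 2 (0.0620), or ANGPTL4 replicate 3 (0.127) or 4 (0.0592), or with length and GC removed (0.217) (range 0.00655 to 0.740). The immediate early list was lower (median log2FC -0.10, adjusted p = 0.0207 and 0.234). The call did not hold without day 6 vehicle replicate 2 (0.123), or ANGPTL4 replicate 4 (0.0622), or with thinning (0.0530) (range 0.00450 to 0.234). The cell cycle list (median log2FC -0.072, adjusted p = 0.0474 and 0.925) lost its call without day 6 vehicle replicate 2 (0.211) or 3 (0.111), or ANGPTL4 replicate 2 (0.234) or 3 (0.518), or with thinning (0.119) or library totals (0.0545) (range 0.000495 to 0.925). The unfolded protein list (median log2FC -0.061, adjusted p = 0.0474 and 0.740) lost it without day 6 vehicle replicate 1 (0.238) or 2 (0.306), or ANGPTL4 replicate 1 (0.248) or 3 (0.127), or with thinning (0.143) or the libraries apart left out (0.253) (range 0.00595 to 0.740).

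The effects of ANGPTL4 at day 6 and day 2 differed for 36 genes, 11 with a higher and 25 with a lower effect at day 6 (30.6% higher). B3galt2, a galactosyltransferase, had a higher effect at day 6 (difference 1.14, SE 0.256, adjusted p = 0.0459 in log2), and Cyc1, of respiratory complex III, had a lower one (difference -0.48, SE 0.0983, adjusted p = 0.0382). B3galt2 lost its call without any 1 of 9 libraries, or in 5 other settings (up to 0.107, with thinning) (range 0.0259 to 0.113), and Cyc1 without any 1 of 11, or in 3 other settings (up to 0.0949, with length and GC removed) (range 0.00820 to 0.108). Over lists, the immediate early and heat shock list was lower (median difference -0.22, adjusted p = 2.57e-05, 0.0301 with an estimated correlation). DESeq2 called 381 genes and limma-voom 19, and the share higher was 60.7% with DESeq2 size factors and 17.4% with library totals alone. The count rose to 312 without day 2 ANGPTL4 replicate 1, 131 without day 6 vehicle replicate 3, 83 without day 2 vehicle replicate 1 and 67 without day 2 vehicle replicate 3. It was 19 without day 6 vehicle replicate 4, 11 without day 2 vehicle replicate 2, 2 without day 2 ANGPTL4 replicate 4 or day 6 ANGPTL4 replicate 3, and 1 without day 2 ANGPTL4 replicate 2 or day 6 ANGPTL4 replicate 2. In edgeR it was 0 without day 2 vehicle replicate 4, day 2 ANGPTL4 replicate 3, day 6 vehicle replicate 1 or 2, or day 6 ANGPTL4 replicate 1 or 4, with 2415 genes at an unadjusted p under 0.05 over all libraries.

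LA was compared with ANGPTL4 directly to ask where the treatments parted. At day 2, Angptl4 (from 21.6 ± 0.590 to 81.7 ± 1.32 CPM, ANGPTL4 then LA; log2FC 1.92, SE 0.0621, adjusted p = 2.04e-21) and Cpt1a (log2FC 0.65, SE 0.0473, adjusted p = 3.04e-11) were higher with LA. Each list below has its adjusted p with an estimated correlation second. In the PPAR list 4 of 40 members were higher, 7 over the list alone (median log2FC 0.037, adjusted p = 1.31e-12, 0.0111). The ribosomal protein list was higher, with 69 of 76 members above 0 and none called (median log2FC 0.22, adjusted p = 1.14e-11 and 0.605). The hypoxia list was higher (1 of 34 members were higher, 3 over the list alone, median log2FC 0.021, adjusted p = 2.75e-06 and 0.220). The oxidative phosphorylation list was higher (median log2FC 0.16, adjusted p = 2.56e-05 and 0.712). Its call was lost without day 2 LA replicate 3 (0.491), or with the libraries apart left out (0.526) (range 1.50e-23 to 0.712). The oxidative stress list was higher too (median log2FC 0.051, adjusted p = 0.00984 and 0.497). The call ended without day 2 LA replicate 3 (0.491), or ANGPTL4 replicate 2 (0.0501) or 3 (0.0701), or with the libraries apart left out (0.526) (range 7.42e-05 to 0.526). In day 2 LA replicate 4 the scores of the ribosomal protein, oxidative phosphorylation and oxidative stress lists (-0.118, -0.159 and -0.000990) lay below all 4 ANGPTL4 libraries (0.0415 to 0.342, -0.0192 to 0.192 and 0.0131 to 0.135). The cell cycle list was lower (median log2FC -0.091, adjusted p = 0.00832 and 0.712). It lost the call without day 2 ANGPTL4 replicate 1 (0.168), or with thinning (0.0546) (range 0.000697 to 0.712). The satellite cell list was lower (median log2FC -0.060, adjusted p = 0.0370 and 0.220). This call was lost without day 2 LA replicate 3 (0.137), or ANGPTL4 replicate 2 (0.0559), 3 (0.0769) or 4 (0.104), or in 3 other settings (up to 0.162, with the libraries apart left out) (range 0.00292 to 0.220). The TGF-beta list was lower (median log2FC -0.053, adjusted p = 0.0460 and 0.412). The call did not hold without day 2 LA replicate 2 (0.203) or 3 (0.124), or ANGPTL4 replicate 1 (0.1497), 2 (0.0502), 3 (0.0701) or 4 (0.0636), or in 4 other settings (up to 0.161, with length and GC removed) (range 0.0134 to 0.412). In all, 12 genes differed at day 2, 8 higher and 4 lower with LA, while DESeq2 called 35 and limma-voom 22. The count was 6 without day 2 LA replicate 2 and 7 without LA replicate 1 or ANGPTL4 replicate 3, but 363 without LA replicate 4, 159 without LA replicate 3 and 102 without ANGPTL4 replicate 4.

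At day 6, LA and ANGPTL4 differed in muscle, lipid and Wnt antagonist lists. Sarcomere transcripts were lower with LA than with ANGPTL4 (51 of 58 members were lower, 53 over the list alone, median log2FC -0.39, adjusted p = 1.34e-49, 0.00108 with an estimated correlation), among them Neb (log2FC -0.68, SE 0.0973, adjusted p = 3.18e-05). Angptl4 (log2FC 3.89, SE 0.0694, adjusted p = 1.42e-29) and Lpl (log2FC 2.77, SE 0.268, adjusted p = 6.96e-07) were higher with LA, and in the PPAR list 18 of 40 members were higher, 21 up and 1 down over the list alone (median log2FC 0.21, adjusted p = 5.07e-36, 1.53e-05). Wnt antagonists were higher with LA (7 of 13 members were higher, 8 up and 1 down over the list alone, median log2FC 0.46, adjusted p = 3.73e-06, 0.00723), led by Sfrp1 (log2FC 2.12, SE 0.289, adjusted p = 1.59e-05). The beta-catenin target list did not pass (median log2FC 0.080, adjusted p = 0.176). Fibroblast markers were higher with LA in the same libraries (9 of 14 members were higher, 10 over the list alone, median log2FC 0.38, adjusted p = 1.99e-09, 0.00108), including Dcn, a matrix proteoglycan (log2FC 0.83, SE 0.113, adjusted p = 2.66e-05). In all, 1809 genes differed, 858 higher and 951 lower with LA (47.4% higher, 62.9% with library totals alone).

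The responses to LA and ANGPTL4 were set side by side across genes. At day 2, 697 genes were called in the same direction with both, 302 higher and 395 lower. The overlap of LA and ANGPTL4 calls, day 2, was 1 with the within-group factor as a covariate (r = 0.671), 282 without day 2 vehicle replicate 4, 316 without LA replicate 3 and 417 without ANGPTL4 replicate 4. Independent lists of these sizes would share 94.3. Simulated unchanged groups with the same vehicle libraries averaged 0.4 and 0.3 calls, too few to compare. With the vehicle libraries split 2 and 2 between the comparisons, lists were smaller (976 and 568 on average). The overlap was 57.8 (SD 37.8 over the assignments) against 11.8 for independent lists of those sizes. The fold changes correlated across genes, which are not independent replicates, with r = 0.682, against 0.562 in simulated unchanged groups and 0.377 with the split vehicle libraries. Their covariance was 0.0486 against 0.0148 simulated and 0.0327 with the split. At day 6, 2 genes were called with both (0.251 for independent lists, and with the split 0.5, SD 1.22, against 0.0532), r was 0.274 against 0.459 simulated and 0.036 with the split, and the covariance was 0.0172 against 0.0149 simulated and 0.0025 with the split.

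**Figure D4:**
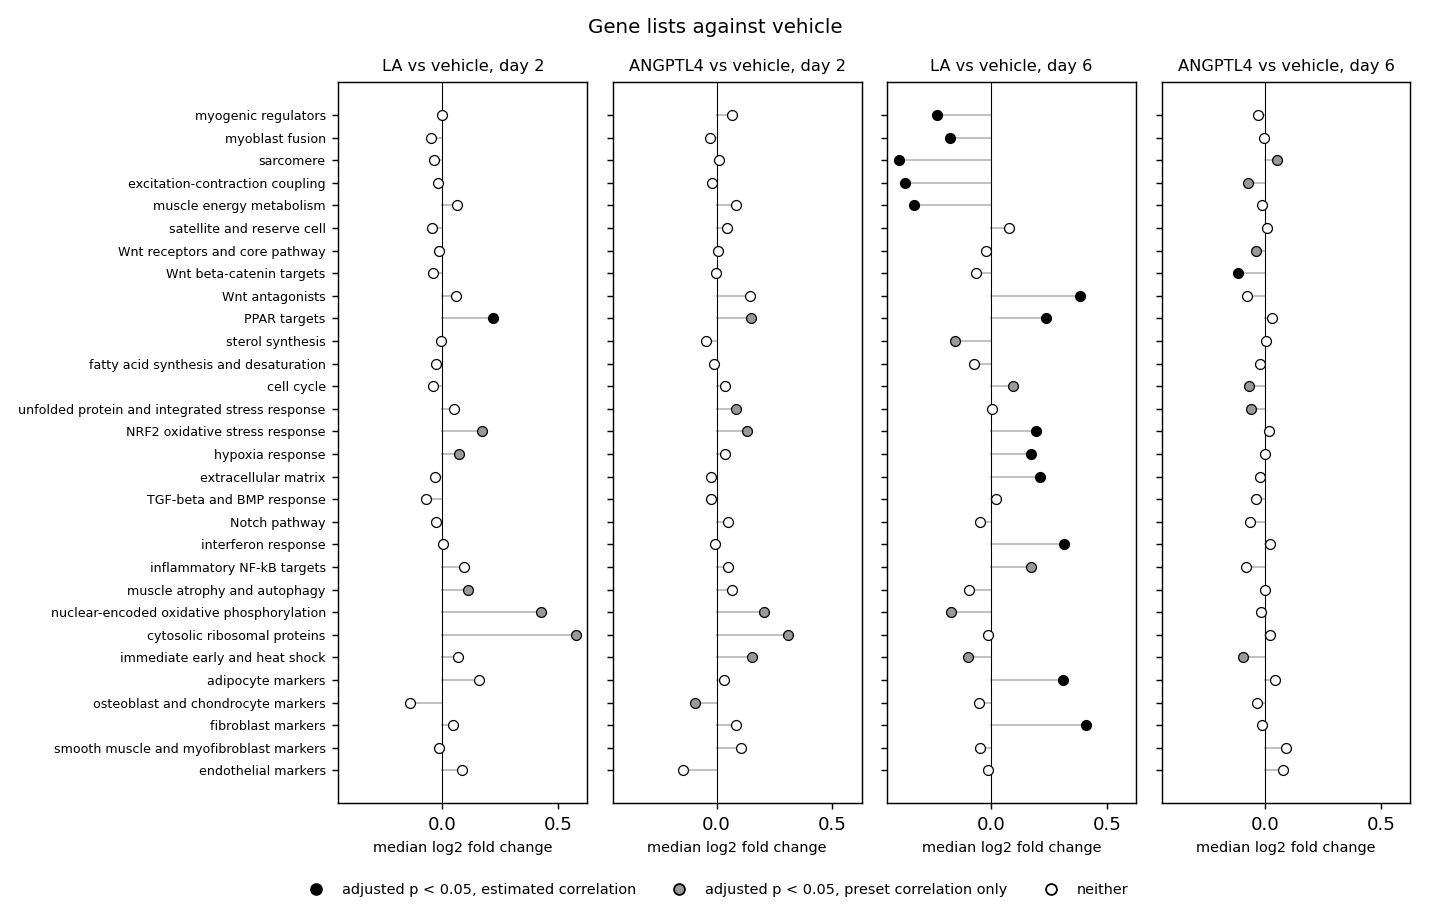
Median log2 fold change of 30 gene lists in the 4 comparisons of a treatment with vehicle, with black points for lists that passed with an estimated correlation, grey points for lists that passed with the preset correlation alone, and white points for the rest. With LA at day 6 the sarcomere list lay at -0.40 and the fibroblast list at 0.41, and with ANGPTL4 at day 6 the beta-catenin target list lay at -0.12.

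Genes that changed with time in vehicle at least 2-fold were followed under treatment, with different vehicle libraries for choosing the genes and for measuring the effect, over 6 ways of dividing them and without a test. At day 6, genes that rose with time (414 on average) had a median log2 fold change of -0.27 with LA (SD over the 6 ways 0.035), and genes that fell with time (276) had 0.21 (SD 0.14; 0.38 with a time change of log2 fold change 2, 0.39 with the stricter filter). With ANGPTL4 at day 6 these medians were 0.00054 (SD 0.024; -0.031 with all vehicle libraries in both steps) and -0.20 (SD 0.094; -0.12 with the stricter filter). At day 2 no median was steady. With LA they were -0.030 (SD 0.017; 0.0070 with all vehicle libraries, -0.092 with the larger time change, -0.051 with the stricter filter) and -0.11 (SD 0.030; -0.27 with all vehicle libraries, -0.054 with the stricter filter). With ANGPTL4 they were -0.056 (SD 0.019; -0.0070 with all vehicle libraries, -0.090 with the larger time change) and -0.23 (SD 0.096; -0.64 with all vehicle libraries, -0.0019 with the stricter filter).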

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

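Of the tests weighed here, those of sequencing depth and of transcript length and GC content for ANGPTL4 at day 2 were chosen after the result was seen, as were the settings that remove the within-group factor, thin the libraries or remove a length and GC trend. The comparison of a treatment's effects between the days was planned.

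The effect of LA differed between day 6 and day 2 by a test of the difference itself for 2554 genes and 19 lists. Values are log2 differences of the effect at day 6 minus that at day 2, with adjusted p from 5.67e-15 to 0.0463 for the genes named. The LA effect was higher at day 6 for C3 (2.42), Lpl (2.29), Ces1a (2.25), Plin4 (2.099), Aoc3 (2.08), Sfrp1 (1.89), Omd (1.87), Angptl4 (1.77), Pdk4 (1.56), Phex (1.51), Ifih1 (1.40) and Gbp7 (1.24). Next were Cpt1a (1.11), Elmo1 (1.06), Lama4 (0.88), Col12a1 (0.87), Col15a1 (0.86), Sfrp2 (0.83), Lipe (0.83), Sfrp4 (0.79), Pdgfra (0.78), Hells (0.70), Pola1 (0.66) and Fzd4 (0.64). Then came Dcn (0.56), Parp14 (0.54), Plin2 (0.54), Col3a1 (0.47) and Ccn5 (0.34). It was lower at day 6 for Rps28 (-1.83), Slc7a11 (-1.82), Naa38 (-1.73), Rps29 (-1.70), Igfn1 (-1.69), Cox8b (-1.63), Pvalb (-1.62), Rplp1 (-1.44), Cox7a1 (-1.34), Atp5k (-1.25), Atp5e (-1.21) and Cox5b (-1.18). Next were Mrln (-0.997), Tcap (-0.91), Myl2 (-0.90), Map1lc3a (-0.75), Cox6a2 (-0.73), E2f2 (-0.72), Porcn (-0.72), Cdkn1a (-0.70), Higd1a (-0.69), Mymx (-0.68), Mymk (-0.67) and Wnt10a (-0.66). Then came Ddit4 (-0.66), Chrng (-0.64), Tm7sf2 (-0.64), Csrp3 (-0.63), Igf2 (-0.60), Hspb1 (-0.59), Mapk12 (-0.56), Ckm (-0.52), Dhcr7 (-0.51), Ebp (-0.48), Acta1 (-0.44) and Hspa1b (-0.44). Last were Btg2 (-0.43), Myod1 (-0.39), Myog (-0.37), Fst (-0.36) and Myh3 (-0.26). Rps28, Slc7a11, Naa38 and Rps29 rose at day 2 (1.35 to 1.57) and were not called at day 6, when Igfn1 and Pvalb fell. The call was lost when 1 library was left out, in the count of the 16 libraries given and with adjusted p up to the value given, for C3 (1, 0.0997), Col15a1 (4, 0.116), Cox6a2 (1, 0.0504), Cox7a1 (12, 0.109), Gbp7 (4, 0.0569), Mrln (13, 0.125), Myl2 (1, 0.0509), Parp14 (1, 0.0503) and Rps29 (1, 0.0622).

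Lists with a higher LA effect at day 6, each with its median difference, adjusted p and adjusted p with an estimated correlation, were Wnt antagonists (0.44, 0.0204, 0.155), fibroblast markers (0.38, 0.00135, 0.0806), interferon response (0.28, 0.0240, 0.155), extracellular matrix (0.28, 3.00e-09, 0.0944), adipocyte markers (0.26, 0.0202, 0.0817), osteoblast and chondrocyte markers (0.24, 0.00895, 0.164), cell cycle (0.15, 0.0202, 0.598), PPAR targets (0.095, 1.21e-05, 0.0806) and hypoxia response (0.060, 0.0116, 0.280). Lists with a lower LA effect at day 6 were cytosolic ribosomal proteins (-0.59, 3.22e-15, 0.264), nuclear-encoded oxidative phosphorylation (-0.54, 1.32e-19, 0.140), excitation-contraction coupling (-0.42, 7.02e-15, 0.0386), muscle energy metabolism (-0.39, 3.62e-07, 0.0806), sarcomere (-0.32, 5.99e-16, 0.0806), immediate early and heat shock (-0.24, 0.00895, 0.0944), myogenic regulators (-0.21, 0.00180, 0.0944), muscle atrophy and autophagy (-0.18, 0.00895, 0.154), sterol synthesis (-0.16, 0.00315, 0.394) and myoblast fusion (-0.086, 0.0429, 0.250). List calls lost when 1 library was left out were, in the same form, myoblast fusion (10, 0.149), Wnt antagonists (1, 0.0579), cell cycle (4, 0.185), hypoxia response (1, 0.0556), interferon response (4, 0.109) and adipocyte markers (1, 0.0628). With all libraries and apart from the estimated correlation, calls were lost for myoblast fusion in 6 other settings (up to 0.0805, with only the compared groups), interferon response with the stricter filter (0.560) or thinning (0.248) and osteoblast and chondrocyte markers with no filter (0.112).

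The effect of ANGPTL4 differed between the days for 36 genes and 8 lists by the same test. It was higher at day 6 for B3galt2 (1.14), Naalad2 (0.59), Fmn1 (0.44), Adgrl3 (0.41) and Tmf1 (0.39). It was lower at day 6 for Doc2g (-1.10), Tmem176b (-1.05), Ccdc85b (-0.73), Tmem147 (-0.65), Bok (-0.60), Hspa1b (-0.55), Phgdh (-0.51), Cyc1 (-0.48) and Fzd2 (-0.42). Adjusted p for these 14 genes ran from 0.0354 to 0.0459, and each lost its call when 1 library was left out, for between 6 and 13 of the 16 libraries, with adjusted p up to 0.129. Of lists, given as before, higher at day 6 was sarcomere (0.066, 0.0362, 0.791). Lists that were lower at day 6 were cytosolic ribosomal proteins (-0.29, 1.31e-09, 0.716), nuclear-encoded oxidative phosphorylation (-0.22, 2.28e-08, 0.716), immediate early and heat shock (-0.22, 2.57e-05, 0.0301), unfolded protein and integrated stress response (-0.15, 0.000905, 0.651), PPAR targets (-0.11, 0.0447, 0.716), NRF2 oxidative stress response (-0.11, 0.0447, 0.716) and Wnt beta-catenin targets (-0.063, 0.0447, 0.333). With 1 library left out, calls lost were, in the same form, sarcomere (5, 0.208), Wnt beta-catenin targets (7, 0.137), PPAR targets (8, 0.147) and NRF2 oxidative stress response (8, 0.110). In the same way, calls were lost for Wnt beta-catenin targets in 3 other settings (up to 0.246, with thinning), PPAR targets in 7 other settings (up to 0.223, with the within-group covariate) and NRF2 oxidative stress response in 4 other settings (up to 0.129, with length and GC removed).

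Single libraries lay far from the others of their group in 9 of 132 combinations of a group and a measure by Dixon's test, and chance marks about 1 in 20 groups, here 6.6. On the second principal component these were the day 2 LA replicate 3 (-19.31) and the day 6 ANGPTL4 replicate 1 (18.695). The share of noncoding genes was 2.54% in day 2 ANGPTL4 replicate 4 and 2.22% in day 6 ANGPTL4 replicate 1. In the latter library the 10 most abundant genes held 7.58% of counts and Plin2 stood at 82.2 CPM. In day 2 vehicle replicate 2, Mymk stood at 462.1 CPM and Ccnd1 at 69.97 CPM. Myc stood at 41.3 CPM in day 2 vehicle replicate 4.

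The genes called with ANGPTL4 at day 2 were weighed first. Thinning keeps expected fold changes, so their median absolute value (0.998 of that before) cannot test unequal depth. The count of calls, tested first, lay between its bounds (602 of 1203 left), and depth stays open. Against transcript length and GC content as the whole cause, 638 of the 1276 calls were left with those trends removed (median absolute log2 fold change 0.268 before and 0.224 after, median SE 0.0704 and 0.0659), at the bound set for it, and a part in the other calls stays open. The values go with a factor that also varies within groups. Its gene loadings, from day 6 libraries alone, correlated with the day 2 ANGPTL4 fold changes at r = 0.548, and with the LA fold changes of day 6 at 0.029. With this factor as a covariate the median absolute log2 fold change went from 0.268 to 0.202 and the median SE from 0.0704 to 0.0780, which left 1 call. An effect of ANGPTL4 itself stays open.

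The higher ribosomal protein transcripts with LA at day 2 had a median log2 fold change of 0.58. It was 0.42 with the length and GC trend removed and 0.58 with the within-group factor as a covariate, which argues against both as the whole cause. Depth stays open, as thinning (0.56) keeps expected fold changes. Reads shared with pseudogenes were not tested and stay open. The list's adjusted p of 0.223 with an estimated correlation leaves a joint shift in some libraries open. The score of day 2 LA replicate 4, the shallowest LA library (9.55 M), was -0.118, within those of vehicle. A response to LA is a hypothesis.

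The lower sarcomere transcripts with LA at day 6 had a median log2 fold change of -0.40. It was -0.40 with the within-group factor as a covariate and -0.35 with the length and GC trend removed, which argues against both as the whole cause. A lower share of muscle cells stays open. Medians of fibroblast markers (0.41, SE 0.092), cell cycle genes (0.097, SE 0.031) and satellite and reserve cell genes (0.077, SE 0.058) were positive. They differed by up to 3.22 SE of the difference, but need not respond alike. A change in the kind of cell that carries the fibroblast markers stays open. An effect of LA on differentiation is a candidate explanation and was found and tested on the same data.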

How the results depend on the processing

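The settings with the within-group factor, length and GC trend, thinning, libraries apart left out and library totals alone were chosen after seeing the data. The count of genes changed with LA at day 6 stayed between 1748 and 2608 in the alternatives with all libraries of the comparison, and between 1609 and 2034 when 1 library was left out (genes changed, LA vs vehicle, day 6). Of 446 named gene results, 377 were called. Of those, 238 kept the call in every alternative with all libraries of the comparison and 257 when any 1 library was left out. Of 9516 named gene values under alternatives, 962 changed the call. By comparison, 67 of 81 called named genes kept the call in all such alternatives for LA at day 6, 19 of 45 for LA at day 2, 56 of 65 for LA against ANGPTL4 at day 6. They were 44 of 49 for time, 49 of 63 for the change of the LA effect, 3 of 9 for LA against ANGPTL4 at day 2, and 0 of 48 and 0 of 3 in edgeR and the other tools for ANGPTL4 at day 2 and day 6. The causes of the changes that follow were not tested.

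With only the compared groups in the fit, counts moved both ways, and the cause was not tested. Genes called were 422 with LA at day 2, 685 with ANGPTL4 at day 2 and 6 for LA against ANGPTL4 at day 2, but 83 with ANGPTL4 at day 6, 2608 with LA at day 6 (genes changed, LA vs vehicle, day 6) and 2124 for LA against ANGPTL4 at day 6 (genes changed, LA vs ANGPTL4, day 6). With the length and GC trend removed they were 1251, 741, 32 for LA against ANGPTL4 at day 2 and 8 for the change of the ANGPTL4 effect. After thinning they were 1195 with LA and 690 with ANGPTL4 at day 2, 0 with ANGPTL4 at day 6 by edgeR (1513 at an unadjusted p under 0.05 before thinning, 87 by DESeq2 and 3 by limma-voom), and lists were 3 with ANGPTL4 at day 6 and 5 for the change of its effect. Without the libraries apart they were 590 with LA at day 2, 10 with ANGPTL4 at day 6, 236 for LA against ANGPTL4 at day 2 and 60 for the change of the ANGPTL4 effect.

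With the within-group factor as a covariate, genes called were 1 with ANGPTL4 at day 2, 7 for LA against ANGPTL4 at day 2 and 0 for the change of the ANGPTL4 effect by edgeR (2415 at an unadjusted p under 0.05 without it, 381 by DESeq2 and 19 by limma-voom), and the day 2 overlap was 1. With DESeq2 size factors they were 1 with ANGPTL4 at day 6 and 56 for the change of its effect, and with library totals alone 1 and 161. DESeq2 called 87 with ANGPTL4 at day 6, 35 for LA against ANGPTL4 at day 2 and 381 for the change of the ANGPTL4 effect, and limma-voom 22 and 19 for the latter pair. The stricter filter gave 64 genes and 5 lists for the change of the ANGPTL4 effect, and r = 0.754 at day 2.

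With an estimated correlation, lists left were 1 with LA at day 2, 0 with ANGPTL4 at day 2 by camera, 1 with ANGPTL4 at day 6, 1 for LA against ANGPTL4 at day 2, 2 for time, 1 for the change of the LA effect and 1 for that of ANGPTL4.

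Replicate numbers were shared between groups, but the 60 pairs of libraries with the same number had a median correlation of their deviations of 0.0088 (-0.309 to 0.303, 8 over 0.1), against 0.0032 for different numbers, and 6 of 24 libraries were closest to their own number, so the numbers did not pair the libraries. With the replicate block, edgeR called 0 genes with ANGPTL4 at day 6, 0 for the change of its effect and 0 in the overlap at day 6.

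With the vehicle libraries split 2 and 2, the overlap was 57.8 at day 2 and 0.5 at day 6, and r was 0.377 and 0.0361. For genes followed over time, LA medians at day 2 were 0.0070 (reversed), -0.092 and -0.051 for genes that rose and -0.27 and -0.054 for those that fell, and at day 6 -0.32, and 0.38 and 0.39. ANGPTL4 medians were -0.0070 and -0.090, and -0.64 and -0.0019, at day 2, and -0.031 for genes that rose at day 6. The settings are named beside the results, apart from -0.32 (the stricter filter).

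When 1 library was left out, genes called ranged from 632 (without day 2 LA replicate 3) to 2456 (day 2 LA replicate 4) with LA at day 2 and from 712 (day 2 vehicle replicate 4) to 1192 (day 2 vehicle replicate 1) with ANGPTL4 at day 2. They ranged from 0 to 7 (without day 6 ANGPTL4 replicate 1) with ANGPTL4 at day 6, from 6 to 363 for LA against ANGPTL4 at day 2 and from 0 to 312 for the change of the ANGPTL4 effect. Lists ranged from 2 (day 6 vehicle replicate 2) to 7 with ANGPTL4 at day 6, with 4 without day 6 vehicle replicate 3 or ANGPTL4 replicate 3 or 4. For LA against ANGPTL4 at day 2 they ranged from 5 (day 2 ANGPTL4 replicate 2) to 10. For the change of the ANGPTL4 effect they ranged from 4 (day 6 vehicle replicate 3) to 10, with 5 without day 2 vehicle replicate 3, day 2 ANGPTL4 replicate 1, day 6 vehicle replicate 2 or day 6 ANGPTL4 replicate 3. The overlap of LA and ANGPTL4 calls, day 2, ranged from 282 (day 2 vehicle replicate 4) to 896 (day 2 LA replicate 4). The correlation of LA and ANGPTL4 effects across genes, day 2, ranged from 0.537 (LA replicate 3) to 0.733 (LA replicate 1). The overlap of LA and ANGPTL4 calls, day 6, ranged from 0 (vehicle replicate 1) to 3 (ANGPTL4 replicate 1). The correlation of LA and ANGPTL4 effects across genes, day 6, ranged from 0.220 (ANGPTL4 replicate 1) to 0.359 (vehicle replicate 3).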

Other observations

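No test in this part was chosen after its result was seen, but thinning and some other settings behind the losses and ranges were chosen after seeing the data. Matrix transcripts rose with LA at day 6. In the extracellular matrix list 23 of 49 members rose and 3 fell, 25 and 3 over the list alone (median log2FC 0.21, adjusted p = 2.08e-10, 0.0473 with an estimated correlation). The fibril-associated collagen Col12a1 rose (log2FC 0.73, SE 0.0741, adjusted p = 2.70e-08). Tenascin Tnc fell (log2FC -0.67, SE 0.166, adjusted p = 0.00782). The interferon list rose (7 of 26 members rose, 8 over the list alone, median log2FC 0.32, adjusted p = 0.000523, 0.0356), including Ifih1, a sensor of double-stranded RNA (log2FC 0.93, SE 0.247, adjusted p = 0.00705, 0.0859 after thinning, range 0.00280 to 0.0859). Of inflammatory NF-kB targets, 7 of 22 members rose and 2 fell, 8 and 3 over the list alone (median log2FC 0.17, adjusted p = 0.00810, adjusted p = 0.0588 with an estimated correlation). The oxidative phosphorylation list was lower (10 of 64 members fell, 9 over the list alone, median log2FC -0.17, adjusted p = 0.000160, adjusted p = 0.558 with an estimated correlation). The cell cycle list was higher (8 of 48 members rose and 1 fell, 8 and 1 over the list alone, median log2FC 0.10, adjusted p = 0.0380, adjusted p = 0.666 with an estimated correlation). The cell cycle list lost its call without day 6 vehicle replicate 1 (0.0776) or 4 (0.0708), or LA replicate 2 (0.304) or 4 (0.189), or with only the compared groups (0.0548) or length and GC removed (0.0596) (range 0.00258 to 0.666). The immediate early list was lower (4 of 28 members fell, 4 over the list alone, median log2FC -0.10, adjusted p = 0.0292, adjusted p = 0.116 with an estimated correlation). The list lost its call without day 6 vehicle replicate 2 (0.0783), or with only the compared groups (0.0548) (range 0.0139 to 0.116). Lists that did not pass with LA at day 6, each with its median log2FC and adjusted p, were satellite and reserve cells (0.077, 0.783), fatty acid synthesis (-0.073, 0.371), the unfolded protein response (0.0055, 0.590), TGF-beta (0.020, 0.923), Notch (-0.047, 0.604), atrophy (-0.10, 0.184) and ribosomal proteins (-0.012, 0.923).

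Over time in vehicle, matrix and fibroblast transcripts rose alongside those of muscle. Lum, a matrix proteoglycan, rose from 1.61 ± 0.615 to 11.1 ± 2.099 CPM (log2FC 2.79, SE 0.195, adjusted p = 2.80e-13). In the extracellular matrix list 27 of 49 members rose and 8 fell, 29 and 8 over the list alone (median log2FC 0.18, adjusted p = 0.00147, adjusted p = 0.411 with an estimated correlation). The fibroblast list rose (7 of 14 members rose and 1 fell, 7 and 1 over the list alone, median log2FC 0.21, adjusted p = 0.0242, adjusted p = 0.215 with an estimated correlation). The call ended without day 2 vehicle replicate 3 (0.0562) (range 0.00864 to 0.215). In the Notch list 3 of 19 members rose and 11 fell, 3 and 11 over the list alone (median log2FC -0.20, adjusted p = 0.00310, adjusted p = 0.173 with an estimated correlation). The atrophy list rose (16 of 23 members rose and 1 fell, 18 and 2 over the list alone, median log2FC 0.24, adjusted p = 0.00223, adjusted p = 0.173 with an estimated correlation). So did the hypoxia list (19 of 34 members rose and 1 fell, 20 and 1 over the list alone, median log2FC 0.25, adjusted p = 0.00310, adjusted p = 0.324 with an estimated correlation).

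Other splits of the same libraries were fitted to ask whether chance could give as many calls. No other split reached the real count of genes with LA at day 2 (1961, reached by 1 of 35 splits, highest other 834) and ANGPTL4 at day 2 (1276, 1 of 35, 102). This also held for LA at day 6 (2237, 1 of 35, 4), LA against ANGPTL4 at day 6 (1809, 1 of 35, 1) and time in vehicle (5930, 1 of 35, 4). It held for the change of the LA effect (2554, 1 of 100, 1000). By the count of splits alone, the share was also under 0.05 for ANGPTL4 at day 6 (3, 1 of 35, 0 by edgeR) and the change of the ANGPTL4 effect (36, 3 of 100, 541). These calls were not steady: edgeR called 0 with the replicate block for both, 0 after thinning for the former, 0 with the within-group covariate for the latter, and 0 without any 1 of 4 and 6 libraries (unadjusted p under 0.05 for 1513 and 2415 genes, 87 and 381 called by DESeq2, 3 and 19 by limma-voom). For LA against ANGPTL4 at day 2 chance cannot be excluded (12, 4 of 35, 535). Splits with 535, 541, 834 and 1000 calls point to a structure of the samples. The within-group covariate left ANGPTL4 at day 2 with 1 call.

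For lists, chance can be excluded for LA against ANGPTL4 at day 6 (19, 1 of 35, highest other 17) and the change of the LA effect (19, 1 of 100, 17). The real count was reached by other splits for LA at day 2 (6, 20 of 35, 13) and ANGPTL4 at day 2 (7, 15 of 35, 10), where chance cannot be excluded either. The same held for LA at day 6 (18, 3 of 35, 18), ANGPTL4 at day 6 (7, 6 of 35, 10), LA against ANGPTL4 at day 2 (8, 11 of 35, 11), time in vehicle (10, 12 of 35, 15) and the change of the ANGPTL4 effect (8, 23 of 100, 10).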
